A study of Mus musculus with 10 samples.

How the data were processed

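Gene expression was measured in 10 samples of cultured mouse cortical neurons, wildtype or ATF4-deficient, treated with sodium arsenite or vehicle. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled with the Affymetrix WT PLUS reagents for mouse arrays. The authors deposited log2 expression values, which per the series design text and the submitters' processing notes were normalized by robust multiarray average (RMA) in Partek Genomics Suite 6.6. RMA corrects the background, makes the distributions of all arrays equal probe by probe and fits 1 value per probe set, so a change shared by most transcripts would be removed from the values. Scanner files were not used here, so the background correction and the quality of single probes were not rechecked.

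The table held 41345 probe sets. The platform annotation gave 23521 of them exactly 1 gene symbol, 1814 several symbols and 16010 no entry. Probe sets of the last kinds name no gene here and were tested separately. Of the probe sets with 1 symbol, 23328 matched a gene of the GRCm38.p6 annotation by Entrez identifier, 193 kept the symbol as given and 0 symbols changed. The build behind the array design is not given in the sources used here, so that annotation served for names and gene order and no coordinates are printed. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays stood for the gene, which left 22180 genes. No genes were removed for low signal. The files hold no detection calls. As a dim reference, 1373 olfactory and vomeronasal receptor genes had a median of 4.52 and a 90th percentile of 6.63 on the log2 scale, and 13524 genes lay above the latter. The number of arrays limits the precision of each value.

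Groups came from the sample titles, with 2 wildtype vehicle, 4 wildtype arsenite, 2 ATF4-deficient vehicle and 2 ATF4-deficient arsenite arrays. The titles call the samples biological replicates and do not say whether these were separate embryos, litters or cultures, so the p-values measure only the spread between these samples. The sex-linked gene Xist was at 7.88 and 11.89 in wildtype vehicle, 11.75 and 6.26 in ATF4-deficient vehicle, and 12.26 and 6.70 in ATF4-deficient arsenite arrays. That argues against these pairs being repeats of 1 sample. Wildtype arsenite replicate 4 (11.9) likewise lay apart from replicates 1 to 3 (8.09, 6.95 and 6.56), among which the spread may be technical. No array duplicated another. No scan date or batch is given in the sources used here. A single limma model (limma 3.58.1 in R 4.3.3) with a mean per group was fitted to all 10 arrays, with 6 residual degrees of freedom and empirical Bayes moderation (prior degrees of freedom 5.08, prior SD 0.124 log2). It gave 5 contrasts: arsenite minus vehicle in each genotype, ATF4-deficient minus wildtype under each treatment, and the interaction, which is the ATF4-deficient response minus the wildtype response. All 10 arrays shared an estimate of spread because most groups hold 2. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. No comparison has 3 or more arrays on each side, so other splits of the samples were not counted. Fold is 2 to the power of the log2 difference, on the scale of RMA values.

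Before the data were examined, 35 gene lists were written for stress pathways, metabolism, synapses and the cell types that a cortical culture can hold. The 34 with at least 3 measured genes were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. Camera was repeated with the correlation estimated from the data. Fry, which asks whether a list's genes move one way on balance without comparing them with other genes, was run too. At an adjusted p of 0.05 the preset correlation gave 13 lists for arsenite in wildtype, 6 for arsenite in ATF4-deficient neurons, 18 for genotype under vehicle, 14 for genotype under arsenite and 7 for the interaction. With an estimated correlation, amino acid synthesis, amino acid transporters, endoplasmic reticulum chaperones and NRF2 targets passed for genotype under arsenite, and 0 lists passed elsewhere. Fry gave 5, 2, 3, 6 and 0 lists in the same order. The lists of the integrated stress response were drawn from general knowledge of ATF4 targets, not from these arrays. Counts within a list are given over all genes tested and adjusted over the list alone.

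The rule for named genes was also fixed before the data were examined. In each contrast it took the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap on any array, leaving out clone and model names and olfactory and vomeronasal receptors. To these it added up to 4 called members of each list, list members given as not past the threshold, and Atf4. Alternatives to this processing were a filter on dim genes, averaging of probe sets, equal array medians, array weights, a variance trend with robust moderation, a replicate block, equal group sizes, models of only the groups compared, a minimum change of 1 log2 unit, and leaving out each array in turn.

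The steps were tested on simulated arrays with the real gene means and spreads, in which 200 of 22180 genes were changed. For changes of 0.5, 1 and 2 log2 units, the share recovered was 37.3%, 85.1% and 100% for arsenite in wildtype, with 7 false calls. It was 28.4%, 91.0% and 97.0% for arsenite in ATF4-deficient neurons, with 10 false calls. For genotype under vehicle it was 26.9%, 68.7% and 100%, with 6 false calls, and for genotype under arsenite 38.8%, 95.5% and 100%, with 12. For the interaction it was 14.9%, 56.7% and 97.0%, with 8. In each contrast 4 of 4 shifted lists were recovered, with 0 false lists. The simulated genes varied independently of each other and the lists were random, so list calls among genes that vary together were not tested. Estimated correlations within the real lists ran from -0.203 for red blood cell genes to 0.774 for metallothionein and metal response genes.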

Results

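RNA from cultured mouse cortical neurons was measured on 10 Affymetrix whole-transcript arrays, which read a transcript with probes placed along its length. The neurons were taken from embryos at embryonic day 14.5 to 15.5 and were wildtype or deficient in ATF4, a transcription factor of the integrated stress response, the pathway that slows protein synthesis in stressed cells and raises ATF4 translation. On day 7 in culture they received 5 µM sodium arsenite, a trivalent arsenic compound that reacts with protein thiols and causes oxidative stress, or vehicle, for 12 hours. There were 2 wildtype vehicle arrays, 4 wildtype arsenite arrays, 2 ATF4-deficient vehicle arrays and 2 ATF4-deficient arsenite arrays. Array medians lay between 6.75 and 6.81 on the log2 scale. The correlation across genes, which are not independent replicates, was 0.973 to 0.990 over all pairs of arrays and 0.980 to 0.990 within groups. ATF4-deficient arsenite replicate 2 stood apart on the first principal component, at 29.4 against -18.2 to 8.70 for the other 9 arrays. As a dim reference, 90% of olfactory and vomeronasal receptor genes lay below 6.63. Of the genes named below, Slc7a11, Tas2r108, Hapln1, Kcnip2, Adamts18, Sfmbt2, Rgs13, Rgs5, Rxfp1, Pcsk1, Pla2g7, Bcan and Slc7a3 had the mean of a compared group under that level, where background limits how much of a change can be seen. Each count below is of genes past an adjusted p of 0.05 in limma, among 22180 genes tested.

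Atf4 itself was read first. Its mean was 9.32 ± 0.34 (SD, n = 2) in wildtype vehicle arrays and 9.69 ± 0.21 (SD, n = 4) in wildtype arsenite arrays, against 7.57 ± 0.12 (SD, n = 2) and 7.62 ± 0.11 (SD, n = 2) in the ATF4-deficient groups. Every ATF4-deficient array lay below every wildtype array. The genotype difference was -1.76 log2 under vehicle (SE 0.18, adjusted p = 0.00876) and -2.08 under arsenite (SE 0.15, adjusted p = 0.000718). The call under vehicle was lost without wildtype vehicle replicate 2 (adjusted p = 0.0792) and without ATF4-deficient vehicle replicate 2 (adjusted p = 0.17), and the call under arsenite was kept without each of the 10 arrays in turn. Arsenite gave no call for Atf4 in wildtype neurons (0.37 log2, SE 0.15, adjusted p = 0.396) or in ATF4-deficient neurons (0.05, SE 0.18, adjusted p = 0.95). The labels do not say which part of the gene was removed, so the remaining signal cannot be assigned to a transcript.

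**Figure D1:**
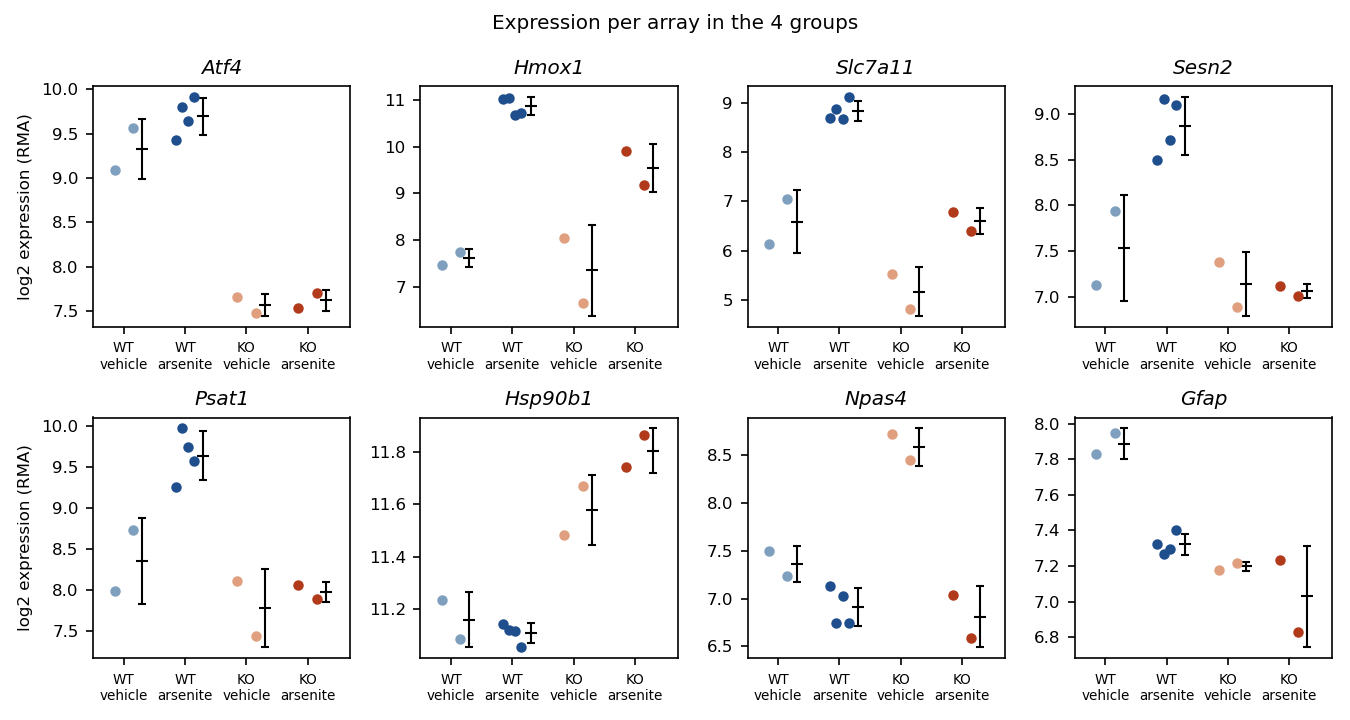
Expression of 8 genes on each array, in log2 RMA units, by group (WT, wildtype; KO, ATF4-deficient); each point is an array, and the black mark with its bar is the group mean and SD. Atf4 was at 7.57 and 7.62 in the ATF4-deficient groups against 9.32 and 9.69 in wildtype, and Hmox1 was higher with arsenite in each genotype.

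The comparison of arsenite with vehicle in wildtype neurons asks what the metalloid does to neurons with ATF4. Hmox1, which encodes the haem-degrading enzyme haem oxygenase 1, rose 9.49-fold (3.25 log2, SE 0.31, adjusted p = 0.00339), from 7.62 ± 0.19 (SD, n = 2) to 10.87 ± 0.19 (SD, n = 4). Slc7a11, the cystine importer that supplies glutathione synthesis, rose by 2.25 log2 (SE 0.25) from a mean of 6.59 ± 0.64 (SD, n = 2), which is under the dim reference. Without wildtype vehicle replicate 1 the rises were 3.11 and 1.80 log2 and neither was called (adjusted p = 0.122 for each). Genes of the integrated stress response rose with them, among them Sesn2, a stress-induced regulator of mTORC1, by 2.53-fold, and Ddit3, which encodes CHOP, by 2.09-fold. The steepest falls were in Rgs4, a regulator of G protein signalling (-1.40 log2, SE 0.16), and Hapln1, a link protein of the extracellular matrix around neurons (-1.33, SE 0.21). In all, 51 genes rose and 56 fell.

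Of the 15 measured amino acid synthesis and one-carbon genes, 4 rose, 0 fell and 11 did not pass. The 4 were the folate enzymes Aldh1l2 (0.84 log2) and Mthfd1l (0.67), the serine synthesis enzyme Psph (0.81) and the branched-chain aminotransferase Bcat1 (0.68). Adjusted over the list alone, 12 were higher and 1 was lower. The list's mean was 0.633 log2 higher (camera, adjusted p = 6.6e-17; adjusted p = 0.127 with an estimated correlation). Of 17 transcription factors and regulators of the integrated stress response, 3 rose, namely Sesn2, Ddit3 and the transcription factor Atf5 (0.58), and 12 were higher when adjusted over the list alone. That list's mean was 0.511 higher (adjusted p = 8.67e-15; adjusted p = 0.127 with an estimated correlation). Of 10 amino acid transporters, Slc7a11 and the cationic amino acid transporter Slc7a1 (1.08) rose, and 7 were higher when adjusted over the list alone (mean 0.667, adjusted p = 9.59e-10; adjusted p = 0.127 with an estimated correlation). Of 12 genes for cytosolic aminoacyl-tRNA synthetases and a tRNA exporter, Lars (0.73) rose, and 9 were higher when adjusted over the list alone (mean 0.463, adjusted p = 2.97e-12; adjusted p = 0.193 with an estimated correlation).

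Hmox1 and Slc7a11 were the 2 of 23 targets of the antioxidant factor NRF2 that rose. Adjusted over the list alone, 7 were higher, and the mean was 0.382 higher (adjusted p = 3.43e-07; adjusted p = 0.0572 with an estimated correlation). The list's median was 0.169, and 7 of its estimates were negative. Among 17 heat shock proteins the co-chaperone gene Dnajb4 rose by 0.43, and the list's mean was 0.228 higher (adjusted p = 1.12e-05; adjusted p = 0.212 with an estimated correlation), with 1 member higher when adjusted over the list alone. Of 23 genes that neuronal activity induces, the transcription factor Egr3 (-0.80) and the activin subunit Inhba (-0.67) fell. Adjusted over the list alone, 9 were lower, and the mean was -0.301 (adjusted p = 4.24e-07; adjusted p = 0.194 with an estimated correlation). Beside these groups, the mean of 13 astrocyte markers was -0.475 log2 (adjusted p = 1.54e-07; adjusted p = 0.377 with an estimated correlation), with 0 members past the threshold over all genes and 6 lower over the list alone. Postsynaptic genes were lower as a list, with a mean of -0.220 over 16 genes, 0 past the threshold and 4 lower over the list alone (adjusted p = 0.000696; adjusted p = 0.623 with an estimated correlation). Presynaptic genes (mean -0.172, adjusted p = 0.0053) and excitatory neuron markers (mean -0.176, adjusted p = 0.0158) were lower with 0 called, and with an estimated correlation their adjusted p was 0.674 and 0.514. The presynaptic call was lost without wildtype vehicle replicate 2 (adjusted p = 0.14) and without wildtype arsenite replicate 3 (mean -0.109, adjusted p = 0.11), as was the excitatory one (0.0522 and 0.0594). Pdgfra, the growth factor receptor of oligodendrocyte precursors, fell by 0.76.

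Other steep changes lay outside the lists. Slc44a5, a choline transporter-like gene, rose by 0.97 and Trim66 by 0.94, and the bitter taste receptor gene Tas2r108 rose by 0.86 from a mean of 5.21 ± 0.07 (SD, n = 2), which is under the dim reference. Falls followed in Nwd2 (-1.29), the sorting nexin Snx7 (-1.17), the potassium channel-interacting protein Kcnip2 (-1.15), Arhgap29 (-1.02), the histone deacetylase Hdac9 (-0.95), Dok5 (-0.93), the guanylate cyclase subunit Gucy1a1 (-0.92) and Ndnf (-0.89). With array medians made equal the split became 26 higher and 50 lower in place of 51 and 56. The count of 107 was 0 without wildtype vehicle replicate 1, 37 without wildtype vehicle replicate 2, 44, 14 and 14 without wildtype arsenite replicates 1, 2 and 3, 63 without either ATF4-deficient vehicle array and 57 without either ATF4-deficient arsenite array.

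The same treatment of ATF4-deficient neurons asks which changes occur with little ATF4. Hmox1 rose here too, by 4.52-fold (2.18 log2, SE 0.36, adjusted p = 0.0215), and Slc7a11 by 1.43 log2 (SE 0.29, adjusted p = 0.0432), with both of its means, 5.166 ± 0.494 and 6.599 ± 0.273 (SD, n = 2 each), under the dim reference. The Hmox1 vehicle arrays lay apart, and without vehicle replicates 1 and 2 the rise was 2.86 and 1.49 log2. Its call was lost without ATF4-deficient vehicle replicate 2 (adjusted p = 0.0767) and without ATF4-deficient arsenite replicates 1 and 2 (0.0968 and 0.0504). The Slc7a11 call was kept without either wildtype vehicle array and lost without each of the other 8 arrays, with a rise between 1.08 and 1.78. Txnip, which encodes a thioredoxin-binding protein, rose by 1.55 log2 and the inducible Hsp70 gene Hspa1a by 1.06. Genes that neuronal activity induces fell, led by the nuclear receptor genes Nr4a3 (-2.13 log2, SE 0.24, adjusted p = 0.00288) and Nr4a2 (-1.38) and by the transcription factor genes Npas4 (-1.77, SE 0.18) and Fos (-1.62, SE 0.21). In all, 140 genes rose and 116 fell.

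Of the 23 activity-regulated genes, 9 fell, 0 rose and 14 did not pass, and 13 were lower when adjusted over the list alone. The list's mean was -0.662 log2 (camera, adjusted p = 7.31e-18; adjusted p = 0.0632 with an estimated correlation), between 8.31 ± 0.01 (SD, n = 2) under vehicle and 7.65 ± 0.10 (SD, n = 2) under arsenite. Of the 23 NRF2 targets, 4 rose, the other two being the thioredoxin reductase gene Txnrd1 (0.78) and Gclc (0.69), which encodes the catalytic subunit of glutamate-cysteine ligase. Over that list alone 7 were higher, and its mean was 0.375 higher (adjusted p = 8.38e-06; adjusted p = 0.0632 with an estimated correlation). Hspa1a and Dnajb4 (0.47) were the 2 heat shock genes of 17 that rose, with 7 higher over the list alone and a mean of 0.349 (adjusted p = 8.38e-06; adjusted p = 0.411 with an estimated correlation), which was 0.232 without ATF4-deficient arsenite replicate 2 (adjusted p = 0.013). The 4 lists of the integrated stress response did not pass here: the mean was 0.05 for amino acid synthesis (adjusted p = 0.624), 0.03 for the transcription factors and regulators (0.901), 0.03 for the tRNA synthetases (0.676) and 0.24 for the transporters (0.315), with Slc7a11 their single called member. The astrocyte markers were at -0.08 on average (adjusted p = 0.466). Microglia and macrophage markers had a mean of -0.139 with 0 called (adjusted p = 0.0369; adjusted p = 0.896 with an estimated correlation), and without ATF4-deficient vehicle replicate 1 or arsenite replicate 2 it was -0.0909 and -0.0272 (adjusted p = 0.203 and 0.549). Without arsenite replicate 1 it was -0.25.

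Among the further genes, Tas2r108 rose by 1.42, Tnfrsf23, a decoy receptor, by 1.35, the protease gene Adamts18 by 1.18, the semaphorin receptor gene Plxnc1 by 1.14, Slc44a5 by 1.09 and Sfmbt2 by 1.08. The lysosomal membrane gene Lamp2, on the autophagy and lysosome list, rose by 0.53. Falls included Rgs4 (-2.02), Hdac9 (-1.78), the neuropeptide gene Adcyap1 (-1.71), the relaxin receptor gene Rxfp1 (-1.34), Rgs13 (-1.31) and Rgs5 (-1.04), a gene on the pericyte list. Nr4a1 (-1.34) was among the 9 activity-regulated genes counted above. The count of 256 was 149 without either wildtype vehicle array, 160 without wildtype arsenite replicate 2, 57 and 51 without ATF4-deficient vehicle replicates 1 and 2, and 123 and 50 without ATF4-deficient arsenite replicates 1 and 2. With only the 4 ATF4-deficient arrays in the model it was 0.

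Calls in the 2 genotypes overlapped. Of the genes that rose, 20 did so in each genotype, where 0.322 would be shared by independent lists of those sizes (one-sided Fisher's exact test, p = 1.61e-31), and 21 fell in each (0.293 for independent lists, p = 2.1e-34). These comparisons share no array, although they share the estimate of spread, and the test treats genes as independent of each other. Of the genes called in wildtype, 90.2% of those that rose and 96.4% of those that fell had the same sign in ATF4-deficient neurons. The share with matching signs was not counted over all genes, across which the changes correlated at r = 0.401 (rho = 0.286). The median share of the wildtype change found in ATF4-deficient neurons was 61.7% for rising genes (quartiles 33.0 and 110) and 67.0% for falling genes (quartiles 44.0 and 105). These genes were selected on the wildtype change, which enlarges it. Among rising genes the median was 28.4% for the 10 on the integrated stress response lists and 76.9% for the other 41. The rising share was 36.2% without wildtype vehicle replicate 2, and the falling share was 25.5% without that array and 110% without wildtype arsenite replicate 3.

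**Figure D2:**
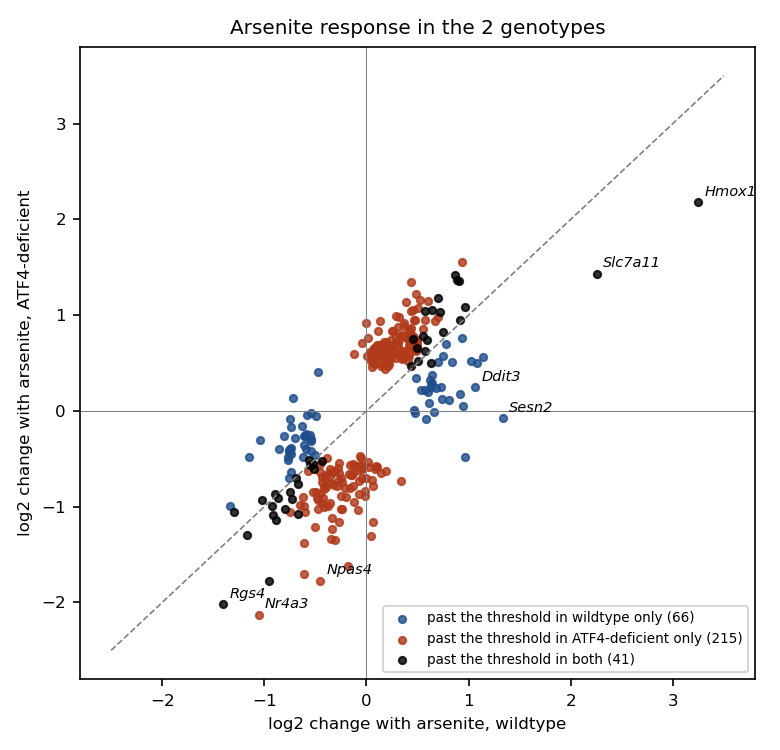
Log2 change with arsenite in wildtype (x axis) and ATF4-deficient neurons (y axis) for the genes past the threshold in 1 or both genotypes; each point is a gene, and the dashed line marks equal change. Hmox1 and Slc7a11 rose in each genotype, Sesn2 and Ddit3 lay near 0 on the y axis at -0.07 and 0.25, and 41 genes were called in each genotype.

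The genotype difference under vehicle asks what lack of ATF4 changes without arsenite. Higher in ATF4-deficient neurons were Rxfp1 (1.70 log2, SE 0.14, adjusted p = 0.00176), the prohormone convertase gene Pcsk1 (1.68) and 2 genes for secretory granule proteins, Scg2 (1.42) and Vgf (1.12). The activity-induced transcription factor genes Fos (1.34, SE 0.21) and Npas4 (1.22, SE 0.18) were higher as well. Lower were Mfge8 (-2.13, SE 0.38, adjusted p = 0.0402), the secreted phospholipase gene Pla2g7 (-2.05), the matrix proteoglycan gene Bcan (-1.74) and Sparcl1 (-1.63), genes that astrocytes are known to express. In all, 40 genes were higher and 56 lower.

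Of the 23 activity-regulated genes, 5 were higher, 0 lower and 18 did not pass. They included Fos, Npas4, Nr4a1 (1.10) and Nr4a2 (0.90). Over the list alone, 12 were higher and 1 lower, and the mean was 0.385 higher (camera, adjusted p = 1.02e-08; adjusted p = 0.223 with an estimated correlation). Of the 13 astrocyte markers, the intermediate filament gene Gfap was lower (-0.69) and the other 12 did not pass over all genes, while 12 were lower over the list alone. The astrocyte list's mean was 7.64 ± 0.25 (SD, n = 2) in ATF4-deficient and 8.58 ± 0.19 (SD, n = 2) in wildtype vehicle arrays, a difference of -0.936 log2 (adjusted p = 1.66e-13; adjusted p = 0.250 with an estimated correlation). This marker difference stood beside the change in each other group named here.

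Other neuronal and glial lists were lower as well. The mean was -0.199 for postsynaptic genes (adjusted p = 0.00114), -0.255 for inhibitory neuron markers (0.00238), -0.196 for progenitor and cycling cell markers (0.00945), -0.170 for presynaptic genes (0.0144), -0.166 for neuron markers (0.0227) and -0.283 for oligodendrocyte lineage markers (0.0358). With an estimated correlation the adjusted p of these 6 lists was 0.387 to 0.557. A single member was called, the presynaptic vesicle protein gene Syn2 (-0.85), and over each list alone 2, 0, 3, 2, 3 and 3 were lower in that order, with 1 neuron marker higher. Without wildtype vehicle replicate 2 the progenitor (mean -0.130), presynaptic, neuron and oligodendrocyte lists had adjusted p values of 0.202, 0.0781, 0.0713 and 0.118. Without ATF4-deficient vehicle replicate 2 the mean was -0.144 for inhibitory markers (adjusted p = 0.0405) and -0.108 for progenitor markers (adjusted p = 0.11), and without ATF4-deficient vehicle replicate 1 the oligodendrocyte list had an adjusted p of 0.0868. Endothelial markers (0.141), microglia and macrophage markers (0.124) and cytokines and chemokines (0.118) were higher as lists with 0 called (adjusted p = 0.0229 to 0.0285, and 0.377 to 0.522 with an estimated correlation). Each lost its call without wildtype vehicle replicate 2 (means 0.103, 0.0637 and 0.0971) and without ATF4-deficient vehicle replicate 1 (0.108, 0.0761 and 0.0707).

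Genes of amino acid supply were lower as lists. Aldh1l2 (-1.09) was the called gene of 15 for amino acid synthesis, with 4 lower over the list alone and a mean of -0.381 (adjusted p = 3.98e-06; adjusted p = 0.317 with an estimated correlation). The neutral amino acid transporter gene Slc1a4 (-0.99) was the called transporter of 10, with 6 lower over the list alone and a mean of -0.582 (adjusted p = 2.73e-05; adjusted p = 0.317 with an estimated correlation). No aminoacyl-tRNA synthetase gene passed, 3 of 12 were lower over the list alone, and the mean was -0.374 (adjusted p = 1.58e-06; adjusted p = 0.358 with an estimated correlation). Without wildtype vehicle replicate 2 the 3 means were -0.231, -0.371 and -0.247 (adjusted p = 0.00799, 0.00254 and 0.00476). The list of transcription factors and regulators did not pass (mean -0.14, adjusted p = 0.244). Chaperones and degradation factors of the endoplasmic reticulum had a mean of 0.219, with 0 of 19 called and 7 higher over the list alone (adjusted p = 2.81e-05; adjusted p = 0.223 with an estimated correlation). NRF2 targets had a mean of -0.272, with 0 of 23 called and 3 lower over the list alone (adjusted p = 4.35e-05; adjusted p = 0.153 with an estimated correlation). Autophagy and lysosome genes had a mean of -0.151 with 0 of 18 called (adjusted p = 0.0146; adjusted p = 0.413 with an estimated correlation), and -0.0759 without ATF4-deficient vehicle replicate 2 (adjusted p = 0.223).

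Further genes higher in ATF4-deficient vehicle arrays were Brinp3 (1.32), Rgs5 (1.29), Adcyap1 (1.19) and the axon guidance gene Slit2 (1.12). Further lower genes were the glutamine transporter gene Slc38a3 (-1.44), Sla (-1.39), the endothelin receptor gene Ednrb (-1.34), the potassium channel gene Kcnq3 (-1.25) and Spon1 (-1.12). The count of 96 was 20 and 0 without wildtype vehicle replicates 1 and 2, 56 and 0 without ATF4-deficient vehicle replicates 1 and 2, and 54 and 52 without wildtype arsenite replicates 1 and 2. With only the 4 vehicle arrays in the model it was 0.

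The genotype difference under arsenite asks what the treated cultures lack without ATF4. Astrocyte markers were lower there too (mean -0.537), and whether that bears on the genes below was not tested. Slc7a11 was lower in ATF4-deficient neurons by -2.24 log2 (SE 0.25, adjusted p = 0.00603), from 8.84 ± 0.21 in wildtype (SD, n = 4) to a level under the dim reference. Lower with it were Eif4ebp1, an inhibitor of translation initiation (-1.92, SE 0.31), the serine hydroxymethyltransferase gene Shmt2 (-1.84, SE 0.23), Sesn2 (-1.81, SE 0.24) and the serine synthesis gene Psat1 (-1.65, SE 0.24). Chaperone genes of the endoplasmic reticulum were higher, among them Hsp90b1 (0.69, SE 0.09, adjusted p = 0.00918). In all, 60 genes were lower and 16 higher, and each of the 25 that differed by at least 1 log2 unit was lower. The balance depended on the fit: with Xist as a covariate, a fit chosen after the data had been seen, 187 were lower and 142 higher, and with array medians made equal 57 were lower and 9 higher.

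Of 15 amino acid synthesis genes, 9 were lower, 0 higher and 6 did not pass, with Aldh1l2 (-1.41) and the proline synthesis gene Aldh18a1 (-1.30) beside Shmt2 and Psat1. Over the list alone 14 were lower, and the mean was -0.967 log2 (camera, adjusted p = 1.3e-27; adjusted p = 0.0433 with an estimated correlation). Of 10 amino acid transporters, 6 were lower, including the large neutral amino acid transporter gene Slc7a5 (-1.66), Slc7a1 (-1.58) and Slc7a3 (-1.47), and 7 over the list alone. The transporter mean was -1.01 (adjusted p = 1.82e-14; adjusted p = 0.0433 with an estimated correlation). Of 12 genes on the tRNA synthetase list, 8 were lower, including Cars (-1.31), Tars (-1.23), Yars (-1.04) and Mars1 (-0.85), and 11 over the list alone (mean -0.804, adjusted p = 8.54e-22; adjusted p = 0.0555 with an estimated correlation). Of 17 transcription factors and regulators, 6 were lower, including Chac1, which degrades glutathione (-1.19), and Atf5 (-0.89), and 12 over the list alone (mean -0.622, adjusted p = 1.52e-15; adjusted p = 0.0781 with an estimated correlation).

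Of 19 chaperones and degradation factors of the endoplasmic reticulum, 3 were higher, 1 was lower and 15 did not pass. Hsp90b1, the disulfide isomerase gene Pdia6 (0.61) and Hspa5 (0.53), which encodes the chaperone BiP, were higher, and Herpud1, a factor of protein degradation, was lower (-0.93). Over the list alone 12 were higher and 1 lower, and the mean was 0.299 (adjusted p = 5.81e-09; adjusted p = 0.0433 with an estimated correlation). Eif2ak3, which encodes the endoplasmic reticulum stress kinase PERK, was 0.75 higher. NRF2 targets had a mean of -0.279 with Slc7a11 the called gene of 23 and 3 lower over the list alone (adjusted p = 3.1e-05; adjusted p = 0.0433 with an estimated correlation). The NRF2 list's median was -0.155, and Slc7a11 is also on the transporter list. Hmox1 did not pass (-1.33 log2, adjusted p = 0.129). Beside these groups the astrocyte markers had a mean of -0.537, with Sox9 (-0.79) called of 13 and 6 lower over the list alone (adjusted p = 5.93e-08; adjusted p = 0.286 with an estimated correlation), and a mean of -0.349 without ATF4-deficient arsenite replicate 2 (adjusted p = 0.000313). The glial transcription factor gene Olig2 was lower by -1.03. Inhibitory neuron markers (mean -0.321, 0 of 13 called and 4 lower over the list alone, adjusted p = 4.72e-06; adjusted p = 0.252 with an estimated correlation) and progenitor and cycling cell markers (mean -0.224, 0 of 15 called and 3 lower over the list alone, adjusted p = 3.1e-05; adjusted p = 0.252 with an estimated correlation) were lower as lists. Without ATF4-deficient arsenite replicates 1 and 2 the inhibitory mean was -0.506 and -0.135 (adjusted p = 7.48e-07 and 0.0201). Oligodendrocyte lineage markers (-0.239, adjusted p = 0.0219) and fibroblast and pericyte markers (-0.163, adjusted p = 0.0446) were lower and excitatory neuron markers higher (0.137, adjusted p = 0.0328), with 1, 0 and 0 called and adjusted p values of 0.286, 0.562 and 0.455 with an estimated correlation. Without ATF4-deficient arsenite replicate 2 these 3 calls were lost (adjusted p = 0.0856, 0.277 and 0.188, with a fibroblast mean of -0.0963). Without wildtype arsenite replicate 4 the oligodendrocyte and excitatory calls were lost (0.0566 and 0.0719), and without wildtype arsenite replicate 3 the excitatory and fibroblast calls were (0.143 and 0.144). The fibroblast call was also lost without wildtype arsenite replicate 2 (mean -0.0975, adjusted p = 0.146) and ATF4-deficient arsenite replicate 1. Of the alternative settings at the preset correlation, 4 kept the fibroblast call and 11 lost it. The activity-regulated genes had a mean of 0.02 (adjusted p = 0.915).

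Other genes higher in ATF4-deficient arsenite arrays were Scg2 (0.97), Tceal9 (0.79), the calcium-binding protein gene Nucb2 (0.67), Rxfp1 (0.67), Zfp994 (0.68) and the taste receptor genes Tas2r137 (0.71) and Tas2r108 (0.70). Slc1a4 was lower by -1.45. The count of 76 was 5 and 1 without ATF4-deficient arsenite replicates 1 and 2, and 36, 37 and 43 without wildtype arsenite replicates 2, 3 and 4. Genotype differences under the separate treatments shared 4 higher genes, against 0.0289 for independent lists, and 8 lower genes, against 0.151 (one-sided Fisher's exact test, p = 1.62e-08 and p = 2.27e-12), and no array. The 8 include Atf4 itself and its neighbour Rps19bp1. The comparisons share the estimate of spread, and the test treats genes as independent of each other. No label says whether vehicle and arsenite cultures came from the same embryos.

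The interaction asks whether the arsenite response itself differed between genotypes. No gene passed in limma (smallest adjusted p = 0.34). At an unadjusted p under 0.05 there were 1330 genes, where 1109 would be reached with no effect, and 1323 with a variance trend and robust moderation. Each of the 10 rising genes on the integrated stress response lists, selected on the wildtype change, had a smaller estimate in ATF4-deficient neurons, with unadjusted interaction p values in limma of 0.00184 to 0.135 and adjusted ones of 0.701 to 0.878. Ddit3 changed by 1.06 in wildtype and 0.25 in ATF4-deficient neurons, Sesn2 by 1.34 and -0.07, Mthfd1l by 0.67 and -0.01, and Atf5 by 0.58 and -0.09. Psph changed by 0.81 and 0.11, Bcat1 by 0.68 and 0.24, and Lars by 0.73 and 0.25. The unadjusted p was above 0.05 for Slc7a11 (2.25 and 1.43), Slc7a1 (1.08 and 0.50) and Aldh1l2 (0.84 and 0.52). As lists, 6 had a more negative change with arsenite in ATF4-deficient than in wildtype neurons at the preset correlation: amino acid synthesis (difference of means -0.586, camera adjusted p = 2.05e-11), the transcription factors and regulators (-0.486, 1.58e-10), activity-regulated genes (-0.361, 2.21e-08), tRNA synthetases (-0.431, 4.65e-08), amino acid transporters (-0.431, 2.59e-05) and cytokines and chemokines (-0.151, 0.0113). Adjusted over each list alone, 7, 4, 7, 0, 1 and 0 of their genes were lower in turn, with 1 activity-regulated gene higher, and each list had an adjusted p = 0.301 with an estimated correlation. The 4 integrated stress response lists rose less in ATF4-deficient neurons. The activity-regulated genes instead fell further there (-0.662 against -0.301 in wildtype). Their vehicle mean was higher (8.31 against 7.925) and their arsenite mean similar (7.648 against 7.623). Cytokines and chemokines changed by -0.132 against 0.0182 in wildtype. The transporter difference was -0.22 without wildtype vehicle replicate 1 and -0.286 without ATF4-deficient vehicle replicate 1 (adjusted p = 0.0148 and 0.00345). The cytokine call was lost without ATF4-deficient vehicle replicate 1 (-0.103, adjusted p = 0.0633) and without ATF4-deficient arsenite replicate 2 (-0.0831, adjusted p = 0.0759). The astrocyte markers moved the other way beside them (0.399, adjusted p = 0.00299; adjusted p = 0.741 with an estimated correlation), and without wildtype vehicle replicate 2, ATF4-deficient vehicle replicate 2 or ATF4-deficient arsenite replicate 1 the difference was 0.268, 0.224 and 0.210 (adjusted p = 0.185, 0.0826 and 0.183).

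**Figure D3:**
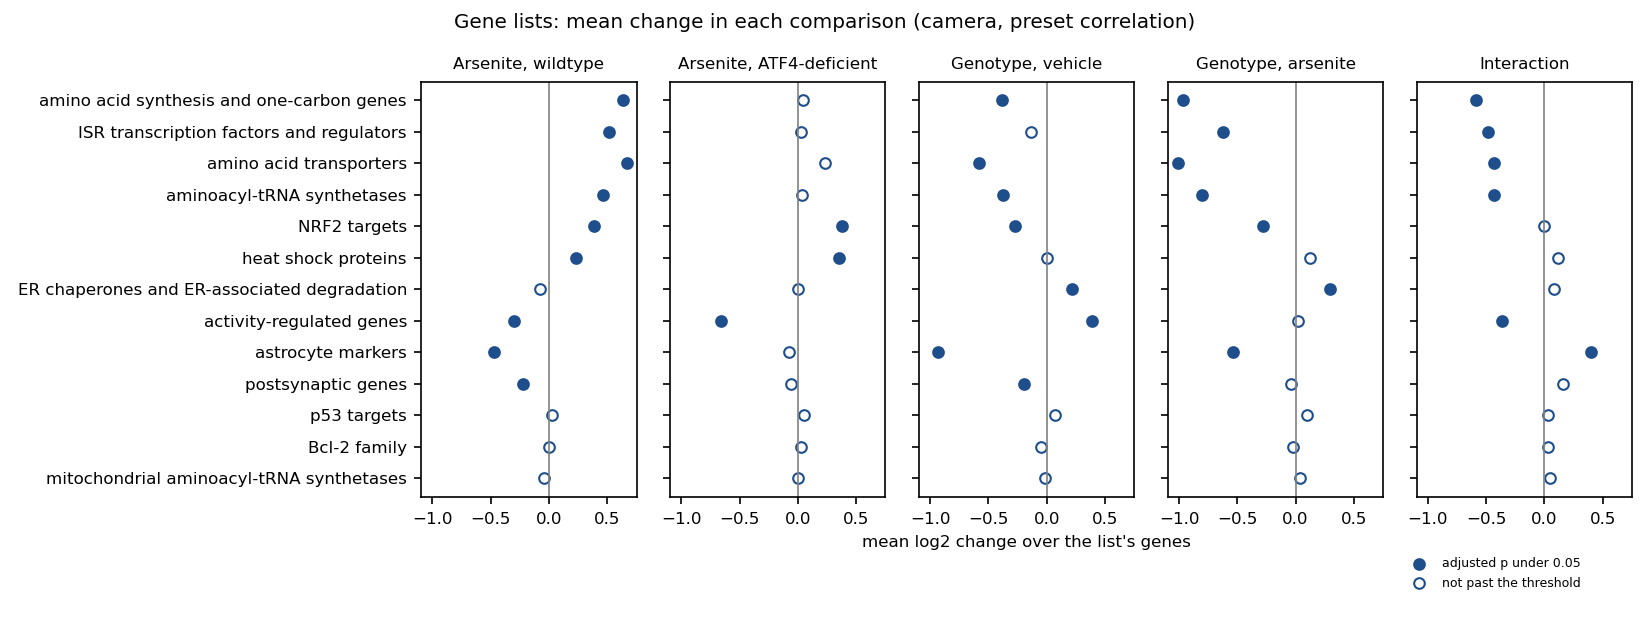
Mean log2 change over the genes of 13 lists (rows) in the 5 comparisons (panels); filled points passed camera with its preset correlation and open points did not. The amino acid synthesis list was at 0.633 with arsenite in wildtype, 0.05 in ATF4-deficient neurons and -0.967 for the genotype difference under arsenite.

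Overlaps between comparisons that share a group were set beside 50 simulations with no effect. These called 0 to 0.02 genes per list on average and so shared 0 calls. A comparison chosen after the overlaps were seen therefore took the top genes of each simulated ranking, as many as were called in the data, which keeps the shared group. The simulated genes varied independently of each other, so overlap from genes that vary together is left out. The highest simulated values are therefore no upper limit for data with no effect. Of the 51 genes that rose with arsenite in wildtype, 13 were also lower in ATF4-deficient arsenite arrays, including Ddit3, Sesn2, Atf5, Psph, Slc7a1 and Slc7a11. Independent lists would share 0.138, and the simulated top genes shared 5.12 on average and 10 at most. With the wildtype arsenite arrays split between the comparisons 5 and 1 genes were called and 0 shared, where at most 1 could be. Of the 40 genes higher in ATF4-deficient vehicle arrays, 23 also fell with arsenite in those neurons, including Fos, Npas4, Nr4a1, Nr4a2, Adcyap1, Rxfp1 and Pcsk1. Independent lists would share 0.209, and the simulated top genes shared 10.9 on average and 18 at most. The 2 ATF4-deficient vehicle arrays are too few to split, so part of this overlap may come from their own spread.

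No member of the p53 target and Bcl-2 family lists passed over all genes in any comparison, and neither list passed camera. Over each list alone a single member passed, a p53 target higher for genotype under arsenite. Simulated changes of 0.5 log2 were recovered for 14.9% to 38.8% of genes, so small changes could be missed. Bbc3, a p53-induced cell death gene on both lists, was at 0.11 log2 with arsenite in wildtype. Lists of mitochondrial aminoacyl-tRNA synthetases, glycolysis, respiratory chain genes and interferon response genes likewise had 0 called members and no list call in the 5 comparisons.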

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

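The tests of the share of astrocytes and of embryo sex were chosen after the data had been seen, and the other tests of explanations in this part were written down before.

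For 7 gene lists the arsenite response differed between genotypes at camera's preset correlation, and for 0 of them with an estimated correlation (adjusted p = 0.741 for astrocyte markers and 0.301 for each of the other 6). The differences of means, ATF4-deficient response minus wildtype response, were -0.586 for amino acid synthesis and one-carbon genes, -0.486 for transcription factors and regulators of the integrated stress response, -0.431 for amino acid transporters, -0.431 for aminoacyl-tRNA synthetases, -0.361 for activity-regulated genes, 0.399 for astrocyte markers and -0.151 for cytokines and chemokines. The last list had 0 called genes (adjusted p = 0.0113) and lost its call without ATF4-deficient vehicle replicate 1 (adjusted p = 0.0633) and without ATF4-deficient arsenite replicate 2 (difference -0.0831, adjusted p = 0.0759). Without single arrays the transporter difference shrank to -0.22 at most, without wildtype vehicle replicate 1, and the astrocyte difference to 0.210, without ATF4-deficient arsenite replicate 1, where its call was lost (adjusted p = 0.183).

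Whether the astrocyte markers bear on the response differences of the other 6 lists was not tested. Under vehicle the astrocyte markers were lower by -0.936 log2 in ATF4-deficient than in wildtype arrays. A single array was not the source: without ATF4-deficient vehicle replicate 2, which moved the list most, the shift was -0.761. Embryo sex was balanced, since each vehicle group held 1 array with Xist above 11 and 1 with Xist below 9. The shift was -0.892 between the arrays with high Xist and -0.979 between those with low Xist, which argues against sex as its source. A lower share of astrocytes would lower their markers alike, and 1 of the 12 markers above background, Slc1a2, lay above 50% of the list's median shift by more than 2 SE, so fewer astrocytes and lower expression within astrocytes cannot be told apart. An effect of ATF4 on astrocytes or their precursors stays open as an untested biological explanation.

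The activity-regulated genes started higher, by 0.385 log2, in ATF4-deficient vehicle arrays. Without wildtype vehicle replicate 2, the array that moved the list most, the shift was 0.342, which argues against a single array as its source. With sex balanced between the vehicle groups, the shift was 0.425 between the arrays with high Xist and 0.346 between those with low Xist, so embryo sex does not account for it. Fewer astrocytes in the same cultures would need activity genes to be higher where astrocyte markers were lower, and the slope within groups was 0.17 instead. That slope and the astrocyte difference give a shift of -0.159 (95% interval -0.422 to 0.104), opposite to the one seen. The slope had a 95% interval of -0.111 to 0.451 on 5 residual degrees of freedom and pooled vehicle and arsenite arrays. Within groups both lists also followed the first principal component (r = -0.917 for astrocyte markers and -0.7 for activity-regulated genes). The slope may therefore reflect what else differed between arrays, so fewer astrocytes are not excluded. Lack of ATF4 may raise these genes, and differences in density or handling between cultures of the separate genotypes, which no label records, stay open beside it.

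In the 4 wildtype arsenite arrays, 7 of 120 values tested had an array set apart from the other 3 by a gap above Dixon's critical value, where chance gives about 1 in 20. Nr4a1 was at 7.36 in replicate 3 against 7.61 to 7.62, and Olig2 at 8.20 in replicate 3 against 8.48 to 8.51. Zfp994 was at 8.07 in replicate 1 against 7.97 to 7.99, and Pdia6 at 9.30 in replicate 1 against 9.19 to 9.21. Shmt2 was at 9.93 in replicate 2 against 9.24 to 9.34. The mean of the Bcl-2 family was 7.42 in replicate 3 against 7.49 to 7.50, and the mean of neuron markers was 10.06 in replicate 3 against 10.20 to 10.23.

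Probe sets outside the gene table held further calls. Of the 1814 with several symbols, 7 were higher with arsenite in wildtype and 7 in ATF4-deficient neurons, and 0 were lower in either. For genotype under arsenite 6 were higher and 1 lower, and for genotype under vehicle and the interaction 0 passed in limma (105 and 51 at an unadjusted p under 0.05). Of the 16010 without an annotation entry, 0 passed in any of the 5 comparisons (limma; 914 to 1521 at an unadjusted p under 0.05).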

How the results depend on the processing

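The fits with Xist as a covariate and the gene list tests with equal array medians were chosen after the data had been seen. In the order arsenite in wildtype, arsenite in ATF4-deficient, genotype under vehicle and genotype under arsenite, the counts of 107, 256, 96 and 76 genes became 14, 47, 27 and 25 with a change of at least 1 log2 unit required, 186, 135, 228 and 40 with array weights, 11, 0, 0 and 41 with only the groups compared, and 12, 108, 23 and 2 with wildtype arsenite replicates 1 and 2 only. The filter on dim genes gave 162 and 193 for arsenite in wildtype and genotype under vehicle, and Xist as a covariate gave 445, 247 and 329 for the last 3. With the replicate block the counts were 17, 286, 165 and 4, the last with 0 higher. Numbers 3 and 4 occur only among wildtype arsenite arrays, so the block fits those arrays exactly and they inform no comparison. Its counts therefore stand beside the 12, 108, 23 and 2 with wildtype arsenite replicates 1 and 2 only, and each was larger. No label says that a number marks a shared embryo, litter or day, and the numbers do not pair the samples throughout: over all pairs of arrays with the same number, deviations from the group means correlated at -0.0555 to 0.403, the highest for the ATF4-deficient arrays, with 0.225 and 0.386 between genotypes for arsenite replicates 1 and 2, and 0.0933 and 0.0186 between treatments for wildtype replicates 1 and 2. Between treatments Xist matched by number in the ATF4-deficient arrays (11.75 and 12.26, 6.26 and 6.70) and wildtype replicate 1 (7.88 and 8.09) and not in wildtype replicate 2 (11.89 and 6.95). Leaving out 1 array at a time gave 0 to 75, 50 to 200, 0 to 99 and 1 to 64; a group left with a lone array is assumed to vary like the others. Fewer arrays leave fewer degrees of freedom, and otherwise the cause was not tested. The interaction stayed at 0 genes under each alternative. Leaving out 1 array moved the share of the wildtype change kept to 36.2 to 86.5% for rising and 25.5 to 110% for falling genes; selection on disjoint wildtype arrays found no gene and gave no value. With an estimated correlation the 13, 6, 18, 14 and 7 gene lists became 0, 0, 0, 4 and 0. Under 15 other settings, each at the preset correlation, the counts of lists stayed within 1.5 times. The lists behind a count and their split into higher and lower could still change. Of 2156 refits of the 114 values for named genes, 1479 kept direction and side of the threshold, 675 kept direction and lost the call, and 2 turned: Atf4 with arsenite in ATF4-deficient neurons was -0.0358 without vehicle replicate 2 and -0.0296 without arsenite replicate 2, in a range of -0.0358 to 0.138. Of the named calls, 0 of 28, 12 of 25, 0 of 26 and 1 of 32 held without every array in turn. Equal array medians moved the median change by less than 0.05 log2. For genes near the receptor genes' 6.63, background limits how much of a fold can be seen.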

Other observations

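The correlations with the first principal component were chosen after the data had been seen, as were the genes named in this part.

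The first principal component held 26.8% of the variance, and over the 10 arrays it correlated with the mean of 10 oligodendrocyte lineage markers at r = -0.938 (permutation p = 3e-05, adjusted 0.00102) and rho = -0.976 (permutation p = 5e-05), and with the mean of 13 astrocyte markers at r = -0.896 (permutation p = 0.00039, adjusted 0.00663) and rho = -0.964 (permutation p = 0.00012). The component was computed from the same genes that supply the lists, so some correlation with list means is built in. Random gene lists were not compared, so these p values do not show that a list follows it more than other genes do. Of 34 lists, 8 passed at an adjusted p of 0.05, so the component was not particular to glial markers. The others were cell cycle control (r = -0.888, adjusted p = 0.0102), presynaptic genes (r = -0.829, adjusted p = 0.0218), proteasome subunits (r = 0.816, adjusted p = 0.0218), inhibitory neuron markers (r = -0.810, adjusted p = 0.0274), heat shock proteins (r = 0.782, adjusted p = 0.03) and postsynaptic genes (r = -0.765, adjusted p = 0.0429), with rho of -0.77, -0.891, 0.673, -0.709, 0.552 and -0.77 in turn. Adjusted over the 34 lists, rho passed for the oligodendrocyte, astrocyte and presynaptic lists. Without the 2 arrays farthest from the median of each list, r was -0.876 for the oligodendrocyte and -0.829 for the astrocyte markers, and after group means were removed it was -0.853 and -0.917. For the other 6 lists in the order above it was -0.764, -0.955, 0.610, -0.426, 0.557 and -0.845 without the farthest arrays, so the relation of the inhibitory markers rested in part on those arrays. After group means were removed r was -0.878, -0.778, 0.774, -0.686, 0.843 and -0.634 for these lists. Glycolysis, which did not pass, was at -0.859, so the relation within groups was not particular to glial markers. Arrays of 1 group differed in glial markers: the astrocyte mean was 8.42 and 7.83 in wildtype arsenite replicates 4 and 3, and 7.75 and 7.38 in ATF4-deficient arsenite replicates 1 and 2.

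Some lists moved with 0 called genes. Proteasome subunits were higher with arsenite in wildtype (mean 0.10 log2, camera adjusted p = 0.00178; adjusted p = 0.681 with an estimated correlation) and in ATF4-deficient neurons (0.16, adjusted p = 0.000422; adjusted p = 0.896 with an estimated correlation). The means were 0.0554 without wildtype arsenite replicate 2 (adjusted p = 0.0931) and 0.0591 without ATF4-deficient arsenite replicate 2 (adjusted p = 0.533), which ended the calls, and 0.269 without ATF4-deficient arsenite replicate 1. They were also higher in ATF4-deficient arsenite arrays than in wildtype ones (0.0965, adjusted p = 0.0425; adjusted p = 0.856 with an estimated correlation), a difference of -0.00862 without ATF4-deficient arsenite replicate 2 and of 0.202 without replicate 1, with the call lost too without wildtype arsenite replicate 1 (0.0745) or 4 (0.063). Cholesterol synthesis genes were lower in wildtype (-0.23, adjusted p = 0.00535; adjusted p = 0.681 with an estimated correlation) and ATF4-deficient neurons (-0.29, adjusted p = 0.00298; adjusted p = 0.896 with an estimated correlation). The wildtype mean was -0.129 without arsenite replicate 1 (adjusted p = 0.163), -0.0604 without vehicle replicate 2 (0.869) and -0.408 without vehicle replicate 1, and the ATF4-deficient mean was -0.176 without arsenite replicate 1 (0.412) and -0.152 without vehicle replicate 1 (0.203).

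The 3 metallothionein and metal response genes averaged -1.0 log2 in ATF4-deficient against wildtype vehicle arrays, with 0 called (camera adjusted p = 0.00138; adjusted p = 0.317 with an estimated correlation). The size depended on single arrays: the difference was -0.375 without ATF4-deficient vehicle replicate 2 (adjusted p = 0.0674) and -1.63 without replicate 1. Under arsenite it was -0.508 (adjusted p = 0.027; adjusted p = 0.398 with an estimated correlation), -0.134 without ATF4-deficient arsenite replicate 2 (adjusted p = 0.309) and -0.881 without replicate 1.

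Rps19bp1, the annotated gene next to Atf4, was lower in ATF4-deficient neurons under vehicle (-0.958 log2, adjusted p = 0.0138) and arsenite (-0.728, adjusted p = 0.0165). If it followed ATF4 activity, it was predicted to rise with arsenite in wildtype, where it changed by -0.245 (SE 0.103, limma adjusted p = 0.404). That argues against a rise with arsenite through ATF4. Dependence on ATF4 at its vehicle level was not tested by this change. DNA of the donor strain around the targeted locus could change several neighbours. Of 99 genes near Atf4, 4.04% differed the same way in both genotype comparisons against 2.49% of other genes, a ratio of 1.62 (one-sided Fisher's exact test, p = 0.235), which is too few to decide. A local effect of the targeted allele on its neighbour was not tested.

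Xist was above 11 on 4 arrays (wildtype vehicle replicate 2, wildtype arsenite replicate 4 and replicate 1 of each ATF4-deficient group) and below 9 on the other 6. Wildtype vehicle replicate 1 and wildtype arsenite replicate 1 were at 7.88 and 8.09, against 6.26 to 6.95 on the remaining 4. Within groups 11 genes followed Xist, Xist included, of which 10 lie on the X or Y chromosome.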
